A study of Arabidopsis thaliana with 4 samples.

How the data were processed

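Gene expression was measured in roots of Arabidopsis thaliana ecotype Col-0 (Columbia) on 4 two-colour microarrays. Per the labels' protocols, seeds were surface-sterilised with isopropanol and 2.5% sodium hypochlorite, inoculated by immersion in the Antarctic bacterial strain Pseudomonas sp. Da-bac TI-8 or left uninoculated, and grown on MS medium at 50% and 22 °C with 16 h of light and 8 h of darkness until day 20. Total RNA was amplified and coupled to Alexa Fluor dyes. On every array the inoculated sample carried Alexa 647 (read in the red channel) and the untreated sample Alexa 555 (read in the green channel). The series describes 4 biological replicates per condition. The dyes were swapped on 0 arrays, so a probe that takes up one dye better cannot be separated from a difference between the conditions. All 4 arrays lay on 1 slide, so a slide effect could not be fitted.

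The deposited scanner tables hold spot brightness as intensity, per the file headers from Agilent Feature Extraction 10.10.1.1, as the median pixel value of the spot and of its local background in each channel. The same deposited tables hold the log10 ratio of red over green, which per the file headers was made after background subtraction with spatial detrending and a linear and lowess dye normalization. The authors also deposited a table of log2 ratios, whose normalization method is not given in the sources used here. Its scale and direction were settled by setting each column against the scanner values of the same array: over spots well above background in both channels, the slope on the loess-normalized log2 ratio used here was 1.09, 1.09, 1.08 and 0.97 for replicates 1 to 4, and the correlations across spots were 0.963, 0.969, 0.966 and 0.999. The column medians were -0.0061, -0.011, 0.0080 and 0.0032. How its columns were centred stays unknown.

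The arrays were read and analysed with limma 3.58.1 and statmod 1.5.0 in R 4.3.3. The background was corrected by normexp with an offset of 50. The plan named mean spot signals; the scanner tables used here carry the median signals, which were used instead. Each array was normalized by loess on its non-control spots, and spots with an outlier mark were dropped (0.0936% to 0.231% of spots per array). A probe was kept when it was well above background in the red channel, or in the green channel, on at least 3 of the 4 arrays. Spots of a probe were averaged, and a gene was represented by its probe with the highest mean intensity, chosen without the ratios. Of the 43803 non-control spots, 34442 were matched to 1 locus through their RefSeq transcript accession without version, in a gene table of the TAIR10.1 assembly, and 9361 kept the name of the probe. The array files name another build, so no genome coordinates are given. After filtering, 6991 genes were tested, 6537 of them with a locus, and 677 had more than 1 tested probe. Among the named genes, MSRB2, PIP1;3 and AT4 each had a further probe with a mean ratio of the opposite sign. LOX2, CYP81F2 and WRKY53 were well above background in green on 1 array each. For VSP1, ACO1, GH3.5, NAS1 and PIP1;4 this held on 2 arrays each.

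The log2 ratio of each gene was tested against 0 with an intercept-only linear model and moderated statistics (limma lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Errors given as SE are the moderated standard errors over 4 arrays. Their number limits the precision: a two-sided exact sign-flip test of a single value on 4 arrays cannot give a p below 0.125. The test was tested on simulated data with 50 changed genes at each of 4 sizes. At a log2 size of 0.5 it recovered 0 of 50 genes, at a size of 1 it recovered 17, at a size of 2 it recovered 49 and at a size of 3 it recovered 50, with 6 false calls among 122. Of 24 simulated lists, the list shifted by -0.5 was called, 1 list in all. Simulated genes were independent of each other, and their noise was centred at 0 and equal on all 4 arrays. In the data the log2 ratios of replicate 4 had an SD of 0.89 across tested genes, against 0.45 to 0.50 on the others. The recovery on the real arrays may therefore differ.

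Before the data were examined, 32 gene lists with 638 entries were fixed, covering hormone, immune, nutrient, metabolic, cell type and reference genes. An entry whose locus is annotated as another gene was dropped, leaving 637. The 24 lists with at least 5 members measured on all 4 arrays were tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01. List medians are given relative to the median of all genes tested, which was 0.20 on the log2 scale and which the alternatives moved to between -0.058 and 0.289. Named genes followed a rule fixed at the same time: with fewer than 5 genes past the threshold in a direction, the 5 genes of that direction with the smallest p among those with a locus, the same sign on all 4 arrays and signal above background in both channels; up to 4 members with the smallest p from each list past its set test and from the auxin, jasmonate, ethylene, salicylate, immunity, iron, phosphate, nitrate and photosynthesis lists; and the reference genes as a group. The wording of the rule leaves open whether the second set of lists applies when some list passes; it was read as applying, and this reading was settled after the genes' values and their behaviour under the alternatives had been seen. The planned lower bounds for genes not well above background in green on any array are not given. For JMT, ETR2, IRT2 and F6'H1 the bound equalled the fitted ratio. The log2 ratios of all genes not well above background in green depend on the background correction.

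The alternatives tried covered the background correction, the normalization within and between arrays, a separate-channel fit, a fit that ignores which channels shared an array, the filter on dim probes, outlier spots, the choice of probe, the prior, the authors' values, each replicate left out, the set test, and a list without its largest member. Of these, loess on the tested probes, centring of the tested genes and array quality weights were added after seeing the data. Lists of leaf and shoot markers, low-energy genes and rapid wound genes were also written after the ratios had been seen, before each was tested. The lists past the set test, the leaf and shoot markers and the wound genes were set against 10000 random lists of tested genes in the same bins of mean intensity; the differences from these were added after seeing the data. A correction for probe composition was not run because probe sequences are not used here, and a block for slide was not run because there was 1 slide.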

Results

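Root transcripts of Arabidopsis plants grown from seeds inoculated with the Antarctic bacterium Pseudomonas sp. Da-bac TI-8 were compared with those of untreated plants at day 20. Each of 4 two-colour arrays carried an inoculated and an untreated root sample. Most probes were not well above background, above all in the untreated channel. In green, 5359, 6647, 5833 and 2366 of 43603 probes were well above background on replicates 1 to 4, and in red 8816, 14426, 8143 and 9356. The median log2 ratio of the tested genes was 0.035, 0.021 and 0.059 on replicates 1 to 3 and 0.68 on replicate 4. Across 6957 genes, which are not independent replicates, the ratios correlated between arrays with Pearson's r from -0.16 (replicates 3 and 4) to 0.36 (replicates 1 and 3).

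The comparison of inoculated with untreated roots asked which transcripts differ 20 days after sowing of inoculated seeds. The gene with the smallest p was AT2G43590, which encodes a chitinase family protein, with a log2 ratio of 1.53 ± 0.19 (SE, n = 4), or 2.89-fold. IGMT4, a methyltransferase of the indole glucosinolate pathway, followed at 1.31 ± 0.21, and AT2G33830, a dormancy- and auxin-associated family gene, at 1.52 ± 0.27. MSRB2, a methionine sulfoxide reductase, had a log2 ratio of 1.16 ± 0.21, and CXXS1, a thioredoxin-like protein, was 2.63-fold higher (SE 0.25 on the log2 scale). In the other direction, MAT3, which encodes an S-adenosylmethionine synthetase, stood at -1.08 ± 0.24. AT2G30020, the protein phosphatase AP2C1, stood at -1.29 ± 0.28, and AT1G20823, a RING-type ubiquitin ligase, at -0.95 ± 0.21. AT3G53730, a histone H4 gene, had a log2 ratio of -0.87 ± 0.19, and AT5G59850, a ribosomal protein S8 family gene, -0.90 ± 0.20. The rule for naming these 10 genes required the same sign on 4 of 4 arrays.

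None of these genes passed the threshold: over the 6991 genes tested, limma gave 0 genes with an adjusted p under 0.05, and the smallest adjusted p was 0.67. At an unadjusted p under 0.05 there were 301 genes, 204 higher and 97 lower, where 349.6 would be expected by chance. The direction was not stable: with the stricter filter on dim probes 54 of 133 were higher. With tested genes centred at their median it was 123 of 489, and with a trend and robust prior 24 of 62. Most other alternatives had more higher than lower genes. Statistics without moderation gave 0 genes past the threshold and 302 at an unadjusted p under 0.05, and limma with a trend and robust prior gave 0 and 62. The same sign on all 4 arrays was found for 1615 genes, or 23.2% of those with 4 values, against 12.5% by chance for independent arrays centred at 0. With array quality weights, chosen after seeing the data, 563 genes passed, replicate 1 carried 72.5% of the weight, and turning the sign of replicate 4 gave 1306 genes. MSRB2 had a log2 ratio of -0.0035 under the stricter filter on dim probes, and 1 of its 3 probes had the opposite sign. Of the 57 named genes, 30 moved by over 1.5 times when some replicate was left out, 20 of them without replicate 4.

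**Figure D1:**
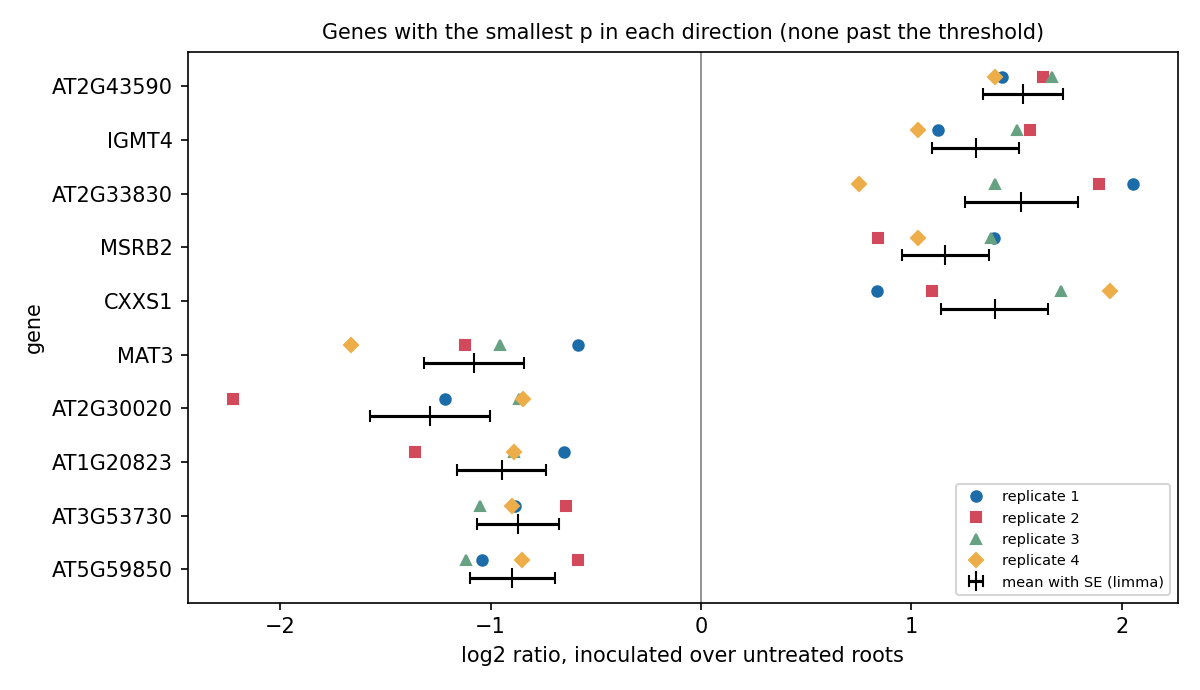
Log2 ratios of inoculated over untreated roots (horizontal axis) for the 5 genes with the smallest p in each direction; coloured symbols are the 4 arrays, and the black bar is the mean with its SE from limma. IGMT4 lies between 1.03 and 1.57 on every array, while AT2G30020 runs from -2.23 to -0.85; none of the 10 passed the threshold.

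Transcripts of cytosolic ribosomal proteins fell as a group relative to the other genes with a preset correlation (camera adjusted p = 1.4e-07), but not with an estimated one (adjusted p = 0.91 with an estimated correlation). Their median relative to that of all genes tested was -0.53, 17 of 21 measured members lay below the all-gene median, and the relative median was -0.51, -0.034, -0.59 and -0.66 on replicates 1 to 4. RPS15 (listed as RPS15A, AT1G04270) had a log2 ratio of -0.74 ± 0.22 (SE, n = 4), RPS6 (AT4G31700) -0.72 ± 0.25 and RPS13A -0.77 ± 0.28, whereas RPS18C stood at 0.59 ± 0.24. Against random genes matched on mean intensity, the list's median differed by -0.37, with -0.52, 0.045, -0.58 and -0.040 on replicates 1 to 4. Without a filter on dim probes the relative median was -0.23 (adjusted p = 0.051, in a range of 1.4e-09 to 0.91 over all alternatives).

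Genes of phenylpropanoid and lignin synthesis also fell as a group with a preset correlation (camera adjusted p = 7.8e-05), but not with an estimated one (adjusted p = 0.91 with an estimated correlation). The relative median was -0.43, with 9 of 10 measured members below the all-gene median. PAL1, the entry enzyme of the pathway, had a log2 ratio of -0.998 ± 0.331, below 0 on 3 of 4 arrays, and CAD4 (AT3G19450), a cinnamyl alcohol dehydrogenase, -0.79 ± 0.21 on 4 of 4. C4H stood at -0.24 ± 0.19 and HCT at -0.35 ± 0.29, or -0.084 without replicate 3 and -0.60 without replicate 1. The relative median was -0.25, -0.32, -0.37 and -0.79 on replicates 1 to 4, and against random genes matched on mean intensity the difference was -0.28, with -0.22, -0.24, -0.36 and -0.25. Without a filter on dim probes the relative median was -0.059 (adjusted p = 0.083, in a range of 1.6e-05 to 0.91 over all alternatives).

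Aquaporins, the water channels of the plasma membrane and tonoplast, fell as a group and had a relative median of -0.48, with 10 of 13 measured members below the all-gene median (camera adjusted p = 0.0044, and adjusted p = 0.98 with an estimated correlation). PIP1;3 (PIP1C) had a log2 ratio of -0.92 ± 0.34, PIP2;2 (PIP2B) -0.50 ± 0.29 and TIP1;1 (GAMMA-TIP) -0.40 ± 0.29, while PIP1;4 stood at 0.62 ± 0.48. Without replicate 3 the first 3 stood at -0.54, -0.17 and -0.096, and without replicate 4 PIP1;4 stood at -0.034. The list's relative median was -1.36 on replicate 3 and between -0.29 and -0.15 on the others. Against random genes matched on mean intensity the list differed by -0.31, with -0.16, -0.085, -1.32 and 0.35 on replicates 1 to 4. Without replicate 3 it was -0.066 (adjusted p = 0.84, in a range of 0.00012 to 0.98 over all alternatives).

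Photosynthesis and chloroplast genes, which mark green or shoot tissue, rose as a group with a preset correlation (camera adjusted p = 8.4e-05), but not with an estimated one, which came to 0.74 (adjusted p = 0.98 with an estimated correlation). The relative median was 0.45, with 29 of 30 measured members above the all-gene median, and the arrays differed in sign, with 0.041, 1.84, -0.55 and 0.78 on replicates 1 to 4. The light-harvesting genes LHCB2.2, LHCA1, LHCB3 and LHCA3 had log2 ratios of 1.87 ± 0.67, 1.32 ± 0.43, 1.19 ± 0.33 and 1.18 ± 0.42. LHCB2.2 stood at 1.14 without replicate 1 and LHCA3 at 0.70 without replicate 2. Against random genes matched on mean intensity the list differed by 0.57, with 0.027, 1.90, -0.53 and 1.303 on replicates 1 to 4. Leaf and shoot markers outside photosynthesis, a list of 7 measured genes written after the ratios were seen, had relative medians of 0.043, 0.43, -0.025 and 0.87 on the same arrays. Without replicate 2 the photosynthesis relative median was 0.075 (adjusted p = 0.65) and without replicate 4 it was 0.32 (adjusted p = 0.050), in a range of 4.8e-12 to 0.98 over all alternatives; with ratios scaled between arrays it was 0.28 (adjusted p = 0.17).

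**Figure D2:**
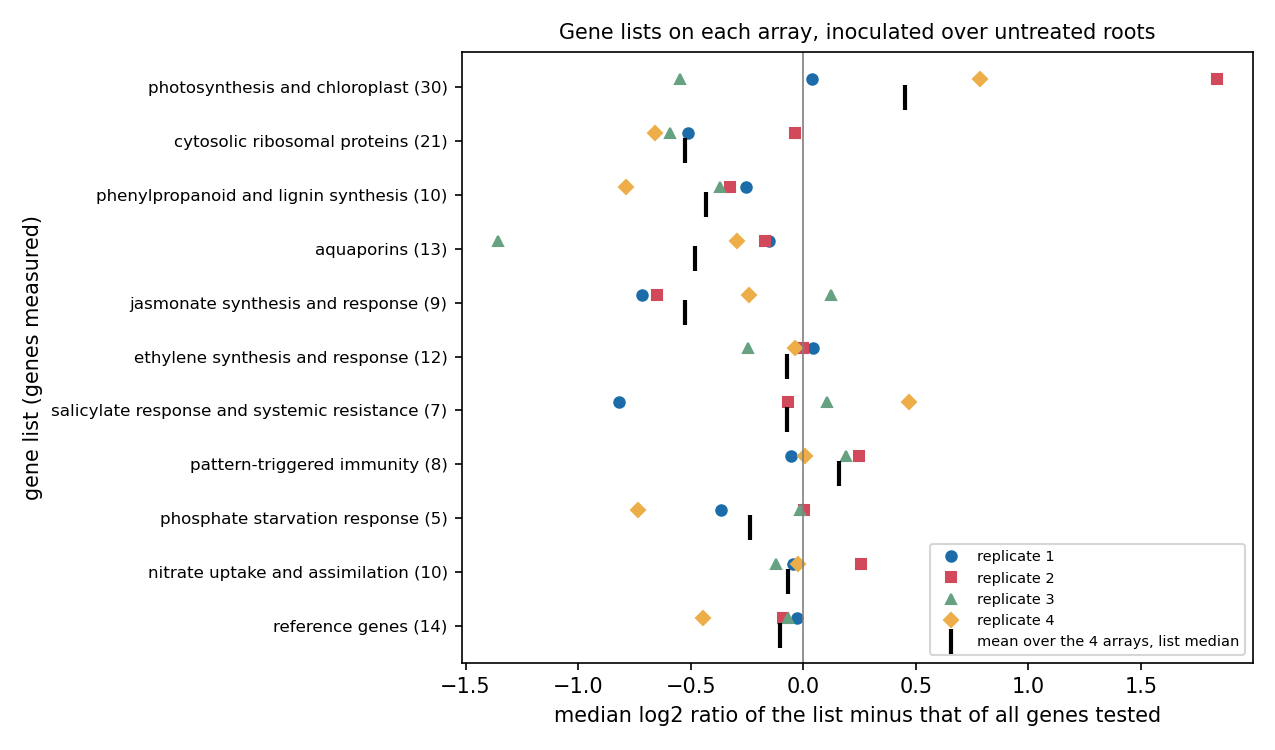
Median log2 ratio of each gene list minus that of all genes tested (horizontal axis) on each of the 4 arrays (coloured symbols) and for the mean ratios over the arrays (black bars), with the number of measured genes in parentheses. The photosynthesis list runs from -0.55 on replicate 3 to 1.84 on replicate 2, while the phenylpropanoid list lies between -0.79 and -0.25 on every array.

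No hormone list with a set test passed it. In the jasmonate list, with 9 measured members, the relative median was -0.52 (camera adjusted p = 0.24). It ran from -0.67 to -0.024 over 23 alternatives. VSP1 had a log2 ratio of 0.61 ± 0.29, LOX2 0.78 ± 0.39 and AOS, which acts early in jasmonate synthesis, -0.41 ± 0.23. Without replicate 4 VSP1 stood at 0.39, and without replicate 2 LOX2 stood at 0.49 and AOS at -0.27. JMT, the jasmonate methyltransferase, was not well above background in green on any array and had a log2 ratio of 0.63 ± 0.25. The ethylene list had a relative median of -0.072 over 12 members (adjusted p = 0.59), a sign that turned under 3 alternatives, with ACO1 at -0.41 ± 0.24, ACS6 at -0.48 ± 0.28 and the chitinase CHIB (AT3G12500) at 0.44 ± 0.34. Without replicate 4 ACO1 stood at -0.19 and CHIB at 0.093, and without replicate 2 ACS6 stood at -0.20. The receptor gene ETR2, not well above background in green, stood at 0.36 ± 0.21, or 0.21 without replicate 4. The auxin list had 3 measured members and no set test. GH3.3, an auxin-conjugating enzyme gene, was not well above background in green and had a log2 ratio of 1.26 ± 0.46, which replicate 4 carried (0.67 without it). GH3.5 (WES1) stood at 0.42 ± 0.29, or 0.10 without replicate 4, and IAA2 at 0.26 ± 0.29, or -0.031 without replicate 3.

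Neither defence list passed its set test. The pattern-triggered immunity list had a relative median of 0.16 over 8 members (camera adjusted p = 0.93), or 0.082 without replicate 4, 0.092 without replicate 2 and 0.0058 with array quality weights. The chitin receptor gene CERK1 had a log2 ratio of 0.53 ± 0.19 with the same sign on 4 of 4 arrays. CYP81F2 stood at 0.63 ± 0.25 (0.41 without replicate 2) and WRKY53 at 0.51 ± 0.22, each well above background in green on 1 of 4 arrays. The zinc finger gene ZAT12 (RHL41) stood at -0.999 ± 0.328, below 0 on 3 of 4 arrays. The salicylate list had a relative median of -0.071 over 7 members (adjusted p = 0.86), a sign that turned under 7 alternatives. GRX480 stood at -0.79 ± 0.28, WRKY70 at 0.67 ± 0.32, EDS1 at 0.63 ± 0.43 and NPR1 at 0.31 ± 0.27. Replicate 4 carried the last 3, which stood at 0.30, 0.055 and 0.023 without it.

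Neither the phosphate nor the nitrate list passed its set test. The phosphate starvation list had a relative median of -0.23 over 5 members (camera adjusted p = 0.26), a sign that turned under 2 alternatives. The phosphate-responsive RNA AT4 (AT5G03545) stood at -0.36 ± 0.20, the acid phosphatase gene PAP17 at -0.37 ± 0.23 and SPX1 at 0.20 ± 0.25. Without replicate 4 AT4 stood at -0.23, and without replicate 3 PAP17 stood at -0.22 and SPX1 at -0.029. SQD1, not well above background in green, stood at 0.21 ± 0.22, or 0.042 without replicate 4. The nitrate list had a relative median of -0.069 over 10 members (adjusted p = 0.93), which turned sign under 6 alternatives. The ammonium transporter gene AMT1;3 had a log2 ratio of 0.63 ± 0.27, the nitrate reductase gene NIA1 0.52 ± 0.41, NIR1 0.38 ± 0.32 and HHO2 (AT1G68670) -0.23 ± 0.20. Without replicate 4, NIA1 stood at 0.22 and NIR1 at 0.056. NIA1 stood at 0.23 without replicate 2 and 0.97 without replicate 1, and NIR1 at 0.62 without replicate 3. In the iron list, with 4 measured members and no set test, ABCG37, a coumarin exporter gene, stood at 0.70 ± 0.26 and NAS1 at 0.42 ± 0.29, or 0.092 without replicate 4. IRT2 and F6'H1 (AT3G13610) were not well above background in green and had log2 ratios of -0.15 ± 0.23 and 0.039 ± 0.194.

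Reference genes had a relative median of -0.10 over 14 members (camera adjusted p = 0.51), which turned to 0.0059 without replicate 4 and to 0.14 with no filter on dim probes. With no background correction the reference genes passed the set test, at -0.29 (adjusted p = 0.023, in a range of 0.023 to 0.98 over all alternatives). The other 13 lists with a set test had relative medians between -0.24 and 0.37 and adjusted p from 0.36 to 0.99. In the xylem and secondary wall list the relative median was 0.090 although the set test pointed lower (adjusted p = 0.99). Of the lists without a set test, cytokinin (4 measured members), gibberellin (5, not all with 4 values), root meristem (2) and heat shock (3) had relative medians of -0.0020, 0.23, -0.18 and -0.029, and the flavonoid and root cap lists had 0 measured members. Over all 32 lists, 267 different loci were tested; 0 passed over all genes and 0 passed adjusted over the list alone, where the smallest p was 0.069. With an estimated correlation 0 lists passed. Dye bias could not be separated from inoculation, because every array had the same dye orientation.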

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

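The array quality weights, the list of leaf and shoot markers, its test against matched intensity and the differences from matched genes were chosen after the ratios were seen; the other tests were planned before their results were seen. Of 73 values examined per array, 9 had 1 array far from the other 3. Chance gives about 1 in 20 for a single value by the critical value used, and the 73 share arrays and genes. Replicate 4 was the distant array in 6 of the 9, replicate 3 in 2 and replicate 2 in 1.

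The median log2 ratio of the tested genes was 0.68 on replicate 4 and 0.021 to 0.059 on the others. If the shift had been limited to dim genes, those brighter than the median gene should have stayed below 0.2; had it run through all genes, they should have reached 0.5. Their median was 0.25, and that of the dimmer genes 0.996, so the value lay between both bounds and did not decide. The filter kept probes that were well above background in red alone, and replicate 4 had the fewest in green (2366). Over the 4 arrays the median of all genes tested, 0.20 as reported, was -0.0054 with no filter. It was -0.058 with the stricter filter. With the filter as reported it was 0.042 with median centring, 0.010 with loess on the tested probes and 0.041 without replicate 4. The median thus moved with the choice of probes, with the normalization and with replicate 4. The medians of replicate 4 alone under these filters were not worked out. No biological explanation was tested for a shift on a single array.

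The relative median of the aquaporin list was -1.36 on replicate 3, far from -0.29 to -0.15 on the others. PIP2;2 (PIP2B) stood at -1.49 on the same array, far from -0.23 to -0.12. The reference genes had a relative median of -0.44 on replicate 4, far from -0.090 to -0.025. The log2 ratio of ACO1 was -1.09 on replicate 4, far from -0.28 to -0.13. That of NAS1 was 1.39 on replicate 4, far from -0.015 to 0.18. That of AT4 (AT5G03545) was -0.73 on replicate 4, far from -0.26 to -0.22. That of SQD1 was 0.73 on replicate 4, far from 0.024 to 0.054. WRKY53 stood at -0.059 on replicate 2, far from 0.66 to 0.74.

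The photosynthesis list was higher over the 4 arrays, with array medians that differed in sign. Of 10000 random lists matched on mean intensity, a share of 1e-04, the smallest they can give, had a median as high. The photosynthesis list lay 0.57 above them. The random lists draw genes independently, while the members of this list had an estimated correlation of 0.74. The share therefore overstates the evidence, and chance with correlated members is not ruled out. The matched lists had a median log2 ratio of 0.085, below the 0.20 of all genes tested. Matching on intensity thus widened the difference from 0.45 to 0.57, which argues against spot intensity as the cause of the higher list. Leaf or shoot tissue in some root samples may contribute, because 7 measured leaf and shoot markers outside photosynthesis had a relative median of 0.33. The SE of the mean over members, which takes them as independent, was 0.11. On replicates 1 to 4 the relative median was 0.043, 0.43, -0.025 and 0.87. However, camera gave p = 0.061 for the markers and p = 0.38 with an estimated correlation. Their relative median was 0.16 without replicate 4, 0.19 without replicate 2 and 0.090 to 0.493 over 20 alternatives, lowest with array quality weights. They lay 0.27 above random lists matched on intensity, of which a share of 0.0061 had a median as high. Those lists again draw genes independently, while the markers had an estimated correlation of 0.41, so the share does not decide how much intensity accounts for. Of the 11 listed, those 7 passed the filter on dim probes, which the red channel alone can satisfy. The brightest had a mean log2 intensity of 8.79 (CER1), 8.39 (PDF1) and 8.36 (ESM1). Under the stricter filter, which asks for both channels on all 4 arrays, 0 were left, so that alternative gave no value. An effect of inoculation stays open, untested.

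For the lists that were lower, shares of 1e-04 (ribosomal proteins, the smallest possible), 0.0166 (phenylpropanoids) and 0.0089 (aquaporins) of 10000 intensity-matched random lists had a median as low. The random lists draw genes independently, while the estimated correlations within the real lists were 0.21, 0.23 and 0.63. The shares therefore cannot rule out that spot intensity, together with chance in correlated members, accounts for the whole. Intensity accounts for part: against the matched lists the differences were -0.37, -0.28 and -0.31, where the relative medians were -0.53, -0.43 and -0.48. On replicate 4 the difference was -0.040 for ribosomal proteins, -0.25 for phenylpropanoids and 0.35 for aquaporins. Dye bias and an effect of inoculation cannot be told apart, because the dyes were swapped on 0 arrays.

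Turning the sign of some arrays gives 8 splits of the 4 pairs, the real one included, too few for a share under 0.05. The real split gave 0 genes past the threshold with limma and the highest of the others 0, so 8 of 8 gave as many. At an unadjusted p under 0.05 the real split gave 301 genes and the highest other 447, with replicates 1 and 3 set against 2 and 4 (3 of 8 gave as many). The set test passed 4 lists in the real split and 6 in the highest other (3 of 8). With array quality weights the real split gave 563 genes, the split with replicate 3 turned 686 and the split with replicate 4 turned 1306 (3 of 8).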

How the results depend on the processing

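Loess on the tested probes, tested genes centred at their median and array quality weights were chosen after seeing the data. Of 21 alternatives, 18 gave 0 genes past the threshold with limma, leaving out each replicate included. No background correction and the scanner software's log ratio each gave 1 gene, changed at least 2-fold: AT3G29970, named after its values were seen, at 1.59 ± 0.20 (adjusted p = 0.037) and 3.32 ± 0.37 (adjusted p = 0.044), against 1.35 ± 0.54 (adjusted p = 0.67) as reported, in a range of 0.037 to 0.999 over the alternatives; its ratio was 0.60 without replicate 4 and 0.51 with array weights. Array quality weights gave 563 genes, 134 of them changed at least 2-fold, with 72.5% of the weight on replicate 1 and 0.842% on replicate 4; turning the sign of replicate 4 gave 1306. The number at an unadjusted p under 0.05, 301 as reported, ran from 62 (trend and robust prior) to 1951 (array weights), and with a replicate left out from 111 (without replicate 2) to 626 (without replicate 4). No replicate block gave 0 genes (377 unadjusted) and 4 lists. Corrections for probe composition and slide were not run; the share of higher genes among those past the threshold has no value where 0 passed. Set tests passed 4 lists as reported, 5 with no background correction, where the reference genes passed as well (-0.29), 2 with no filter (photosynthesis, and root hair genes at 0.22, which had not passed as reported), 2 with array weights (ribosomal and phenylpropanoid), 0 with an estimated correlation, 0 with fry, and 3 to 4 with a replicate left out. The 4 lists kept their sign under all 24 alternatives, though the prior, estimated correlation and fry reuse the same ratios and cannot turn it. With an estimated correlation their medians were unchanged (-0.53, -0.43, -0.48 and 0.45) and no call was made; nor was one with fry, which asks another question, whether a list's genes differ from 0 and not from the other genes. With no filter on dim probes the calls ended at -0.23 (ribosomal), -0.059 (phenylpropanoid) and -0.012 (aquaporin). Aquaporins also lost the call with median centring (-0.40), the stricter filter (-0.28), the mean of a gene's probes (-0.27), loess on the tested probes (-0.28) and array weights (-0.20). Photosynthesis lost it with scaled ratios (0.28) and array weights (0.15). With a replicate left out, aquaporins ran from -0.70 to -0.066 and photosynthesis from 0.075 to 0.79. Among lists that had not passed, signs turned with no filter for ethylene (0.080), salicylate (0.028), phosphate (0.014), nitrate (0.026) and reference genes (0.14). With a replicate left out, ethylene ran from -0.23 to 0.0084, salicylate from -0.18 to 0.18, phosphate from -0.46 to 0.0065, nitrate from -0.14 to 0.022 and reference genes from -0.27 to 0.0059. Ethylene was 0.016 with array weights. Salicylate was 0.033 with no background correction, 0.047 with the smaller offset, 0.038 with the software's ratio, 0.072 with the authors' values and 0.016 without its largest member. Nitrate was 0.043 with no background correction, 0.12 with the software's ratio, 0.069 with median centring and 0.027 with loess on the tested probes. Of 57 named genes, 46 kept their sign throughout, again counting alternatives of the prior, which reuse the same ratios. MSRB2 was -0.0035 under the stricter filter. With array weights HCT was 0.11, LOX2 -0.065, EDS1 -0.11, IRT2 0.082, SPX1 -0.085, NIA1 -0.40 and NIR1 -0.066. IRT2 was 0.048 with the software's ratio and 0.027 with scaled ratios. F6'H1 (AT3G13610) was -0.00050 with the smaller offset, -0.13 with median centring, -0.23 with loess on the tested probes and -0.16 with centred genes, where SPX1 was -0.0034. With a replicate left out, PIP1;4 ran from -0.034 to 0.95, IAA2 from -0.031 to 0.51, IRT2 from -0.24 to 0.036, F6'H1 (AT3G13610) from -0.026 to 0.11 and SPX1 from -0.029 to 0.37. The cause was not tested for any of these. The median green signal was 357 to 440 per array and that of negative controls 351 to 428. In red these were 52 to 93 and 48 to 90. This limits what either channel can measure for dim probes.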

Other observations

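All tests in this part were chosen after the ratios had been seen, except the set tests of the root hair and sugar lists. Neither of those lists passed as reported; with no filter on dim probes the root hair list did, at a relative median of 0.22. Of 7 measured root hair genes, 5 lay above the all-gene median, with a relative median of 0.37 (camera adjusted p = 0.36). The expansin gene EXPA7 had a log2 ratio of 0.76 ± 0.47 (SE, n = 4), RHS13 0.74 ± 0.40, and RBOHC (RHD2), the oxidase needed for hair growth, 0.57 ± 0.28. Replicate 4 carried EXPA7, at 2.67 against -0.065 to 0.31 on the others, and RBOHC (RHD2), at 1.51 against 0.18 to 0.35. RHS13 was 2.05 on replicate 1, 1.09 on replicate 4 and -0.32 to 0.13 on the others. In the sugar transport and sucrose list the relative median was 0.29 over 8 members (camera adjusted p = 0.38). The asparagine synthetase gene DIN6 (ASN1) stood at 1.47 ± 0.59, DIN10 at 0.87 ± 0.38, SUS3 at 0.75 ± 0.39 and the sugar transporter gene STP4 at 0.54 ± 0.20. DIN6 was 2.31 and 3.44 on replicates 2 and 4, and DIN10 1.78 and 1.45, the arrays on which the leaf and shoot markers had their highest relative medians (0.43 and 0.87). SUS3 was 2.28 on replicate 4 and 0.030 to 0.57 on the others.

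AT2G30020 and AT1G20823, among the lower genes, led to the hypothesis that rapid wound and elicitor responses may be weaker in inoculated roots. Of 16 other measured genes of rapid wound, touch and elicitor responses, 14 lay below the all-gene median, with a relative median of -0.38. The zinc finger gene ZAT6 had a log2 ratio of -0.83 ± 0.23, SZF1 -0.93 ± 0.45 and the deadenylase gene CAF1b -0.58 ± 0.26. Without replicate 2 SZF1 stood at -0.48 and CAF1b at -0.37, and SZF1 was 0.68 on replicate 3. Of the 16, limma gave 0 past the threshold over all genes and 0 adjusted over the list alone. Camera gave p = 1.1e-06 for the list, and p = 0.073 with an estimated correlation. The relative median was -0.27, -0.74, 0.067 and -0.998 on replicates 1 to 4, and it ran from -0.63 to -0.066 over 21 alternatives. The leaf and shoot markers stood at 0.043, 0.43, -0.025 and 0.87 on the same arrays. Those markers are dim and most of the wound genes brighter, which moves the lists apart on replicate 4: against random genes matched on mean intensity the wound list differed by -0.25, with -0.24, -0.68, 0.085 and -0.55 on replicates 1 to 4, and the markers by 0.042, 0.41, -0.016 and 0.62. A share of 0.0082 of the random lists had a median as low as the wound list. They draw genes independently, while the wound list had an estimated correlation of 0.18, so the share does not decide how much intensity accounts for. The table of all genes had been looked at before the list was written, so the test is not independent of it, and handling at harvest and inoculation were not separated. The pattern-triggered immunity list, fixed before the data were examined, did not fall as a group. It had a relative median of 0.16, with 5 of 8 members above the all-gene median and 3 below (camera adjusted p = 0.93). The 3 below were ZAT12 (RHL41) at -0.999, WRKY40 at -0.80 and PEN3 at 0.12. On replicates 1 to 4 the list's relative median was -0.054, 0.25, 0.19 and 0.0092. It was not set against genes matched on mean intensity, so it does not decide on the wound hypothesis.

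AT2G33830 and DIN6, among the higher genes, are induced when sugar runs short, so a low-energy response in inoculated roots is a candidate explanation. However, DIN6 was highest on the arrays where the leaf and shoot markers were highest, while AT2G33830 was lowest on replicate 4 (0.75). A list of low-energy genes had a relative median of 0.199 over 14 measured genes (camera p = 0.056, and p = 0.17 with an estimated correlation), which was 0.11 without replicate 4 and ran from 0.11 to 0.34 over 21 alternatives. On replicates 1 to 4 it was 0.27, 0.10, 0.024 and -0.075. The all-gene median subtracted on replicate 4 was 0.68, against 0.021 to 0.059 on the others. On that array the dimmer genes had a median of 0.996 and the brighter genes 0.25. The low-energy list was not set against genes matched on mean intensity. Its low value on replicate 4 therefore cannot be read against the leaf and shoot markers. However, 7 of the 14 had been noted when the hypothesis was formed, MEE14 (1.06 ± 0.38, and 0.69 without replicate 4), DYL1 (0.66 ± 0.28, and 0.45 without replicate 2) and BCAT-2 (0.55 ± 0.20) among them. The test was limited to the 7 others after the value of 0.199 had been seen. Over these 7 the relative median was -0.036 ± 0.109 (SE of the mean over members, taken as independent), with 3 above and 4 below the all-gene median. The first bound, a median of 0 or less, would have counted this value against the hypothesis; once the value was known the bound was moved to below 0 by more than the SE, here and for the wound list, where either bound gives the same outcome. The value is within 1 SE of 0, so the value seen over the whole list rested on the genes that had prompted it.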
